A study of Mus musculus with 8 samples.

How the data were processed

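Gene expression was measured in 8 mouse induced pluripotent stem (iPS) cell clones with Affymetrix mouse 430_2 3'-IVT arrays, 1 array per clone. Per the labels, the clones came from fibroblasts of reprogrammable mouse embryos that carry doxycycline-inducible Oct4, Sox2, Klf4 and c-Myc, and 4 clones were derived with ascorbic acid and 4 without. They were grown in serum medium with LIF and doxycycline on irradiated feeder fibroblasts. Before RNA extraction, per the labels' protocols, the cells were preplated to remove feeders. Groups and clone numbers were taken from the labels, which call the 4 clones of each group biological replicates. The labels do not say whether clones came from separate embryos or cultures, so p-values measure the spread between these clones. No batch or scan day was given in the labels.

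The deposited values are signal intensity per probe set on a linear scale. The submitters' processing notes name GCOS, the Affymetrix operating software; its version, algorithm and settings are not given in the sources used here. The values themselves show that each array was scaled so that its mean after trimming 2% at each end is 500. Present and absent calls were not used here. All 8 columns of the table were matched to samples by the labels.

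Of 45101 probe sets, 64 are array controls and were left out, 34945 are annotated to 1 gene symbol, 932 to several and 9160 to none. Symbols were checked against a RefSeq gene table of assembly GRCm38.p6 through their Entrez identifiers. A match was found for 99.4% of the single symbols and 0 symbols were renamed. No coordinates are given, because the files name no genome build. Probe sets with several symbols or none were not tested under a gene name.

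Signals were transformed as log2(signal + 16), so fold changes are on that scale and understate the changes of dim genes. Scaling between arrays was kept as deposited under a rule set beforehand: the array medians had to lie within 0.2 log2 of each other, and they spanned 0.199, just inside the limit. The 40% of probe sets with the lowest mean over all arrays were left out, which corresponds to a signal of about 93.7. The brightest probe set stood for each gene, and 13125 genes were tested out of 18193 with a probe set.

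Groups were compared as with minus without ascorbic acid. Each gene was tested with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. An adjusted p for a gene comes from this fit over all tested genes unless another setting or the list alone is named. The mean log2 value of Meg3, Rian and Mirg in each clone was compared by a two-sided exact permutation test over 70 assignments of the clones. Gene lists fixed beforehand were tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the 18 of 19 lists that had at least 3 tested genes. The list counts are also given after adjustment over the list alone. Drawings were made with matplotlib 3.10.9.

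The design, gene lists, threshold and the rule for named genes were fixed before the data were examined. The rule takes every Dlk1-Dio3 gene with a probe set. It takes the genes past the threshold whose groups are fully separated, up to 12 with the largest rise and 12 with the largest fall. From every other list it takes up to 4 members past the threshold, or the 2 with the smallest p where none passes. Where fewer than 10 genes pass, it adds the 10 with the smallest p. Xist, the Y-linked genes, Pou5f1, Nanog, Sox2 and Klf4 are named in any case. Genes named outside this rule are said to have been chosen after their values were seen.

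The scripts were tested on simulated data with 13125 genes and 4 arrays per group. Of 50 genes changed at each size, 48% were called at 0.5 log2, 88% at 1, 96% at 1.5 and 100% at 2.5. All sizes were changed in the same simulated data set, where many genes passed. With few genes passing, as in the real comparison, the Benjamini-Hochberg limit on p is stricter. These shares are therefore no measure of what the real comparison could call. In 20 simulated data sets without change, 0 genes and 2 lists were called. Genes were drawn independently there, while list members were correlated in the real arrays (estimated correlation 0.29 for the fibroblast and feeder-cell markers). The simulated count of lists is therefore no measure of false list calls in the real comparison. The number of arrays limits the precision of the real comparison.

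The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter or a 60% filter on dim probe sets, the mean of a gene's probe sets, and leaving out the _s_at and _x_at probe sets, which can read several transcripts. Others were eBayes without the trend, with robust estimation or with array weights, the clone number as a replicate block, leaving out each clone in turn, camera with an estimated correlation, and fry. Testing every probe set under its own identifier and repeating the 35 splits of the clones after quantile normalization were added after the data had been seen.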

Results

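Expression was profiled in 8 mouse iPS cell clones from reprogrammable fibroblasts, 4 derived with ascorbic acid (vitamin C) and 4 without, to ask how the supplement affects the transcriptome of the resulting clones. Array median signals lay between 134 and 156. The correlation of log2 signals between arrays was 0.979 to 0.985 and covered about the same range within groups and between them. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 1.14 to 1.28. No 2 arrays were duplicates: the median absolute log2 difference of any pair was at least 0.128.

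The clones derived with ascorbic acid had much higher levels of the maternally expressed noncoding RNAs of the imprinted Dlk1-Dio3 domain on chromosome 12. Meg3, a long noncoding RNA also called Gtl2, rose 5.34-fold on its brightest probe set, from a signal of 1304 ± 534 without to 6723 ± 1645 with ascorbic acid (SD, n = 4 each; limma, adjusted p = 0.00324). That probe set is of the _x_at class, which can read several transcripts. Rian, a host of small nucleolar RNAs, rose 6.40-fold, from 364 ± 144 to 2319 ± 413 (SD, n = 4 each; limma, adjusted p = 0.00042). In both genes each of the 4 clones with ascorbic acid lay above all 4 without. The domain was examined first because earlier work ties its silencing in mouse iPS clones to their developmental potential.

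Mirg, a microRNA host in the same domain, had a signal of 686 ± 50.9 with and 383 ± 132 without ascorbic acid on its brightest probe set (SD, n = 4 each), a log2 difference of 0.87 ± 0.18 (SE) that did not pass the threshold over all genes (limma, adjusted p = 0.412). Its other probe set read 885 ± 190 with and 103 ± 52.8 without, a log2 difference of 3.01 (limma over all probe sets, adjusted p = 0.000683). With the mean of the probe sets the log2 difference was 1.38 for Meg3 and 1.98 for Rian, both still called, and Mirg was called too (1.94, adjusted p = 0.00694), as it was without clone 3 of the group without ascorbic acid (1.07, adjusted p = 0.00679). The paternally expressed Dlk1 read 458 ± 108 with and 294 ± 56.9 without (SD, n = 4 each; limma, adjusted p = 0.749), a log2 difference of 0.60 ± 0.18 (SE) with an exact permutation p of 0.0571 and a limma p of 0.00550 over the list alone, which has 1 tested gene. These values are from the brighter Dlk1 probe set, and the other, below the dim limit, was at -0.085 ± 0.27 log2 (SE). Dlk1 was the only member of the paternal list with a probe set in the annotation used here, so that list was not tested as a set. Rtl1 and Dio3 were not analysed here.

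The per-clone mean of Meg3, Rian and Mirg was 11.10 ± 0.19 log2 units with and 9.12 ± 0.51 without ascorbic acid (SD, n = 4 each). The difference of 1.99, or 3.97-fold, had an exact two-sided permutation p of 0.0286, the smallest this design can give. The lowest clone with ascorbic acid (10.92) was above the highest without (9.77). All 3 genes passed when adjusted over the list alone and 2 over all genes, and the list shifted upward in camera (adjusted p = 2.49e-13; adjusted p = 0.0547 with an estimated correlation). The call of Meg3 was lost in eBayes without the trend (adjusted p = 0.136) and with robust estimation (0.0842), while Rian passed under every alternative.

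**Figure D1:**
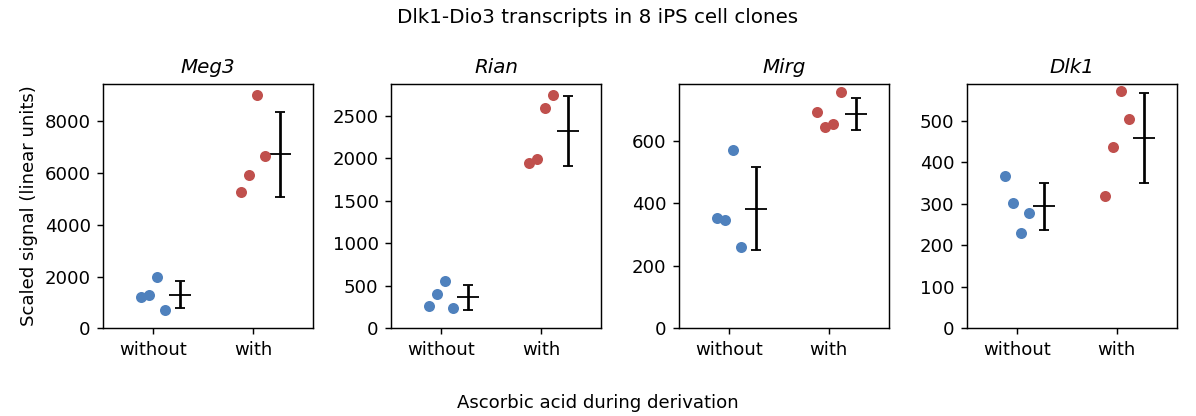
Signal of Dlk1-Dio3 genes in each of the 8 clones (y axis, linear array signal from 0), by derivation with or without ascorbic acid; points are clones and bars are mean ± SD. For Meg3 the clones with ascorbic acid lie between 5252 and 9036 and those without between 699 and 2000.

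The probe sets of these genes pointed the same way but differed widely in size. All 11 Meg3 probe sets were higher with ascorbic acid, by 0.29 to 2.87 log2, and 7 had an unadjusted limma p under 0.05. All 4 Rian probe sets were higher, by 0.73 to 2.68, and both Mirg probe sets were higher. Over the 3 genes, all 14 probe sets without an _s_at or _x_at suffix were higher.

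**Figure D2:**
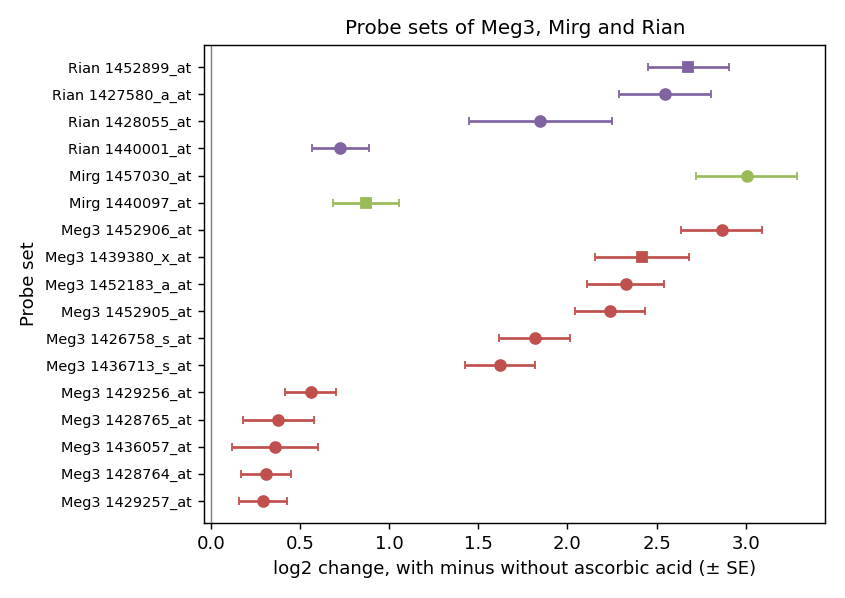
Log2 difference, with minus without ascorbic acid, of each probe set (y axis) of Rian, Mirg and Meg3 (x axis, log2 units; points are estimates and bars standard errors; squares mark the probe set that stood for the gene). The 11 Meg3 probe sets lie between 0.29 and 2.87, all above 0.

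Outside this domain 1 further gene passed. Tcf15, a basic helix-loop-helix factor of early embryonic cells, rose 2.20-fold, from 769 ± 230 to 1663 ± 92.9 (SD, n = 4 each; limma, adjusted p = 0.0285). In total 3 of 13125 genes passed, 3 higher and 0 lower with ascorbic acid. In limma 765 genes had an unadjusted p under 0.05 (402 higher, 363 lower), where 656 are expected by chance; the 34 other splits of the same clones gave 323 to 1745, and 7 of them more than 765. The groups were fully separated in 476 genes, 3.63%, against 2.86% by chance, and 4 of the other splits separated more.

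The call of Tcf15 was close to the threshold. It was lost under quantile normalization (adjusted p = 0.0543), without the dim filter (0.0949), without the trend (0.259), with robust estimation (0.0618) and with array weights (0.0706). Leaving out any single clone except clone 3 without ascorbic acid also lost it (0.0628 to 0.183); without that clone the adjusted p was 5.03e-05.

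Of the genes next in rank none passed the limma test. Mcts2, an imprinted retrogene that lies inside H13 on chromosome 2, read 1295 ± 211 with and 736 ± 85.7 without (adjusted p = 0.0620). Its host H13, which encodes a signal peptide peptidase, went the other way on its brightest probe set, 439 ± 79.4 with and 697 ± 67.3 without (adjusted p = 0.367). Of the 6 H13 probe sets 3 were higher with ascorbic acid, the only other one above the dim limit was at -0.058 ± 0.17 log2 (SE), and the mean of the probe sets above that limit gave -0.36. Mcts2 passed with the 60% filter (0.0439), with array weights (0.0454) and without clone 1 with ascorbic acid (0.0162). Plk3 read 443 ± 60.9 with and 276 ± 12.4 without (adjusted p = 0.234), Mymx 2292 ± 60.3 and 1811 ± 148 (0.367), and Ubald1 1059 ± 96.3 and 804 ± 39.6 (0.383). Lower with ascorbic acid, also short of the threshold, were Ly75 (787 ± 95.7 against 1180 ± 177) and the germline linker histone H1f6 (66.0 ± 15.0 against 152 ± 29.8), both at an adjusted p of 0.383. Errors in these values are SD with n = 4 per group.

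**Figure D3:**
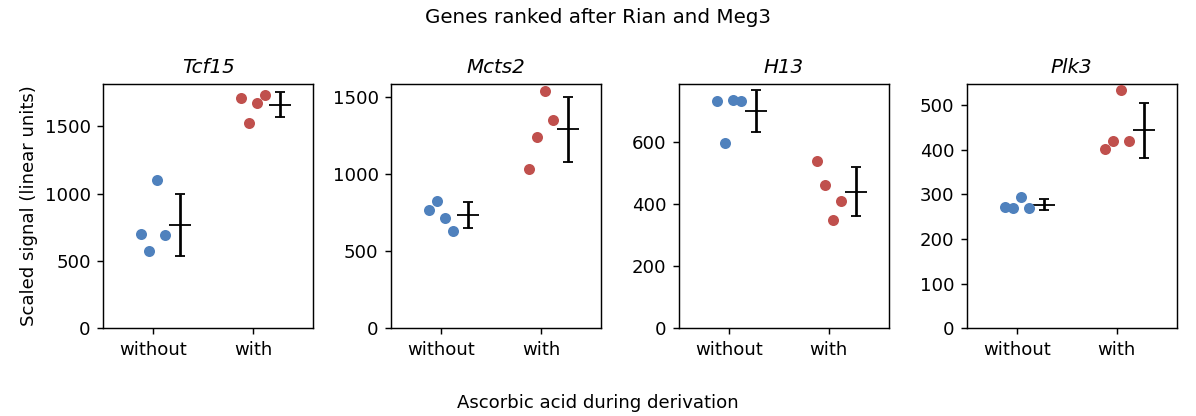
Signal of Tcf15, Mcts2, H13 and Plk3, which ranked after Rian and Meg3 by p, in each of the 8 clones (y axis, linear array signal from 0); points are clones and bars are mean ± SD. Tcf15 (mean 1663 with, 769 without ascorbic acid), Mcts2 and Plk3 are higher with ascorbic acid and H13 is lower, and of these Tcf15 passed the threshold over all genes.

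Among the 50 tested imprinted genes outside the Dlk1-Dio3 domain, 21 were higher and 29 lower, with a median log2 change of -0.05 and no shift as a set (camera, adjusted p = 0.852). None passed over all genes, and 10 had an unadjusted limma p under 0.05; 3 passed when adjusted over the list alone. These were Mcts2, H13 and Zdbf2, the last named after its values were seen (565 ± 101 with, 348 ± 54.5 without, SD, n = 4 each; adjusted p = 0.616 over all genes, 0.0108 over the list). A test for change in either direction, fry's mixed p, was past the threshold for this list (adjusted p = 0.00366).

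The core pluripotency factors were highly expressed in both groups, with no difference past the threshold. Pou5f1 (Oct4) read 10295 ± 948 with and 11283 ± 292 without (adjusted p = 0.844), and Nanog 8948 ± 891 and 9709 ± 294 (0.844). Sox2 read 14333 ± 529 and 15002 ± 335 (0.902), with a log2 difference of -0.07 that turned to 0.038 under quantile normalization. Klf4 read 10272 ± 1072 and 10865 ± 707 (0.908). Errors are SD with n = 4 per group; doxycycline was in the medium, and whether these probe sets read transgene RNA was not analysed here.

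Of 47 pluripotency genes, 15 were higher and 32 lower with ascorbic acid, and 0 passed, over all genes or adjusted over the list alone; 10 had an unadjusted limma p under 0.05. Tbx3 had a log2 change of -0.28 (limma, adjusted p = 0.616) and Klf2 of -0.30 (adjusted p = 0.697). As a set the list shifted lower by a median of -0.08 (camera, adjusted p = 0.00178; adjusted p = 0.589 with an estimated correlation). The median was -0.055 without clone 4 with ascorbic acid, -0.052 under quantile normalization and -0.051 under median centring (adjusted p = 0.0228 in the last). Beside this shift stand the fibroblast and feeder-cell markers, which were also lower, and the share of array signal in the 100 brightest probe sets, which was 6.07% to 7.79% with and 6.60% to 8.36% without ascorbic acid.

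Fibroblast and feeder-cell markers were lower with ascorbic acid in 41 of 46 genes, with a median log2 change of -0.16 (camera, adjusted p = 3.88e-07; adjusted p = 0.589 with an estimated correlation). None passed over all genes or adjusted over the list alone, and 8 had an unadjusted limma p under 0.05. Postn, a matrix protein, had a log2 change of -0.38 and the transcription factor Twist1 one of 0.52. All 8 tested collagens on this list were lower, with a median of -0.26. The per-clone mean of the markers did not separate the groups (difference -0.13, exact two-sided permutation p = 0.171), and without clone 3 with ascorbic acid the median was -0.097.

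Genes of the primed state, as in epiblast cells after implantation, were higher in 14 of 22 members and lower in 8, with a median log2 change of 0.09. Tcf15 rose, and it was the 1 member past the threshold over all genes and adjusted over the list alone. The list shifted upward (camera, adjusted p = 0.0325; adjusted p = 0.589 with an estimated correlation). The call was lost without clone 1 (adjusted p = 0.0590, median 0.044) or clone 4 with ascorbic acid (0.202, median 0.048) and without clone 1 of the other group (0.408, median 0.028). It was also lost without the dim filter (0.107, median 0.048), with the mean of a gene's probe sets (0.0648, median 0.041) and without the trend (0.0715). The fry mixed p of the list was past the threshold (adjusted p = 0.0171), while fry's test for a shift in 1 direction was not (adjusted p = 0.627). Tcf15, at 1.14 log2, had the largest change of the list. The member with the next smallest p, Pou3f1 (named after its values were seen), was at 0.40 (limma, unadjusted p = 0.00858). The list was not tested without Tcf15, so how far both set calls rest on this gene stays open.

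**Figure D4:**
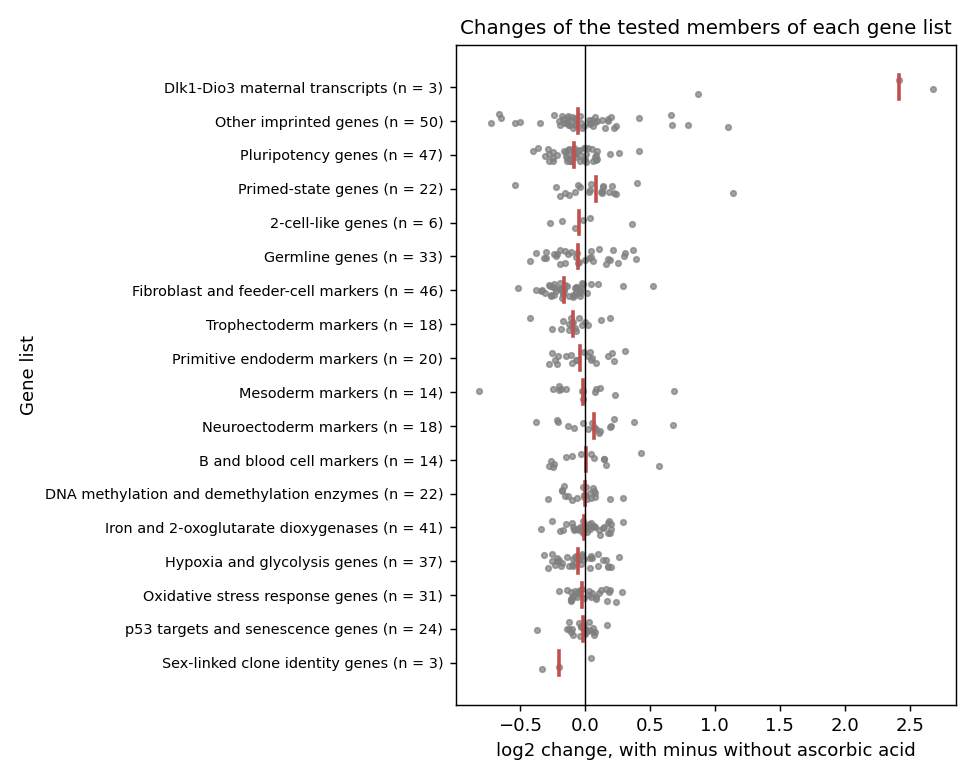
Log2 change, with minus without ascorbic acid, of the tested members of each gene list (x axis, log2 units; each point is a gene and the vertical bar the median of the list). The Dlk1-Dio3 maternal list (median 2.42) stands apart, and the other lists tested as sets have medians between -0.20 and 0.09.

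No shift was found by camera for lineage and germline lists, and 0 of their members passed over all genes or adjusted over the list alone. Trophectoderm markers were higher in 3 and lower in 15 of 18 genes (median -0.09, adjusted p = 0.329), with Rhox9 at -0.42 and Wnt7b at -0.18. Primitive endoderm markers were higher in 9 and lower in 11 (median -0.03, adjusted p = 0.417), with Cst3 at -0.23 and Sparc at -0.21. Mesoderm markers were higher in 5 and lower in 9 (median -0.02, adjusted p = 0.852), with Fgf8 at -0.81 and Lmo2 at 0.69. Neuroectoderm markers were higher in 12 and lower in 6 (median 0.07, adjusted p = 0.417), with Sox1 at 0.68 and Tubb3 at 0.38. B and blood cell markers were higher in 7 and lower in 7 (median 0.01, adjusted p = 0.852), with Laptm5 at -0.26 and Cd74 at -0.27. Germline genes were higher in 15 and lower in 18 (median -0.05, adjusted p = 0.607), with Stag3 at -0.15 and Ddx4 at 0.25. Genes of the 2-cell-like state were higher in 2 and lower in 4 (median -0.04, adjusted p = 0.852), with Calcoco2 at -0.27 and Zfp352 at 0.36. All values are log2 changes.

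Lists tied to known actions of ascorbic acid gave no shift either, with 0 members past over all genes or adjusted over the list alone. The vitamin keeps the iron of iron and 2-oxoglutarate dioxygenases reduced, a family that includes the TET enzymes that oxidise 5-methylcytosine. Of 41 such enzymes, 20 were higher and 21 lower (median -0.0025, adjusted p = 0.436), with Tet1 at 0.20 and Fto at 0.20. These are RNA levels, which do not test an action on the iron of the enzymes, and enzyme activity was not measured here. DNA methylation and demethylation enzymes were higher in 11 and lower in 11 (median 0.0010, adjusted p = 0.852), with Gadd45a at 0.30. Hypoxia and glycolysis genes were higher in 12 and lower in 25 (median -0.05, adjusted p = 0.294), with Mxi1 at 0.20 and Pfkp at -0.25. Oxidative stress response genes were higher in 14 and lower in 17 (median -0.02, adjusted p = 0.852), with Hmox1 at 0.28 and Atf4 at 0.24. Genes of the p53 response and senescence were higher in 11 and lower in 13 (median -0.01, adjusted p = 0.852), with Cdkn1b at 0.17 and Sesn2 at -0.11. For the dioxygenase, methylation enzyme and oxidative stress lists the median and the mean, whose sign camera followed, lay on opposite sides of 0.

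Sex-linked genes were read as a check on the clones. Y-linked Eif2s3y gave a signal of 418 to 3934 in all 8 clones and Uty 65.8 to 797, without a difference between groups past the threshold (limma, adjusted p = 0.953 and 0.970); both were lowest in clone 2 with ascorbic acid. The brightest Xist probe set, of the _s_at class that can read several transcripts, read 628 to 836, and the other Xist probe sets had group mean signals of at most 21.3. Kdm5d and Usp9y fell below the filter on dim probe sets, at group means of 77.4 to 90.7 and 82.5 to 94.3. As a list the 3 tested sex-linked genes had a median log2 change of -0.20 (camera, adjusted p = 0.852), with 0 past over all genes or adjusted over the list alone.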

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

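Chosen only after the result was seen were the tests of cross-hybridising probe sets, feeder RNA and Mcts2 probe sets reading H13. So were those of imprinted genes as a class, residual feeder cells and splits after quantile normalization. The account of the split with the most genes by its brightest probe sets also came after. The others were set before, but the window of the copy number test is drawn around Tcf15, Mcts2 and H13, whose changes had been seen.

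Of 100 groups of 4 clones tested for a sample far from the rest, 8 (8%) held one, where chance gives about 5%. H13 read 597 in clone 2 without ascorbic acid, against 730 to 733 in the others. Stag3 read 1109 in clone 4 with ascorbic acid, against 1227 to 1234. Clone 2 with ascorbic acid read low for Twist1 (161, others 212 to 217), Wnt7b (509, others 714 to 746) and Usp9y (15.2, highest of the others 114). Fto read 1518 in clone 4 without ascorbic acid, against 1327 to 1350. Plk3 read 295 in clone 3 without ascorbic acid (others 268 to 271) and 534 in clone 3 with it (others 400 to 420).

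A signal also appeared in a probe set outside the gene comparison. A probe set without a gene name in the annotation used here read 485 ± 101 with and 103 ± 27.1 without ascorbic acid (SD, n = 4 each), a log2 change of 2.08 (limma over all probe sets, adjusted p = 0.000598).

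The Dlk1-Dio3 maternal RNAs were far higher with ascorbic acid. Array scaling is argued against, since the array medians spanned only 0.199 log2. The 3-gene difference was at least 1.99 log2 under the other scalings, which could hardly have changed it with medians so close. Cross-hybridisation is argued against, since the probe sets without an _s_at or _x_at suffix had a median change of 1.36. RNA from feeder fibroblasts is argued against too, since their markers went the other way (median -0.16, bootstrap 95% interval -0.19 to -0.08). The count of genes does not exclude chance: 2 of the 35 splits of the 8 clones, the real one included, gave as many as the real 3, the highest other giving 51. That split set clones 1, 2 and 4 with ascorbic acid and clone 2 without it against the rest and follows a property of the arrays at the bright end: the 100 brightest probe sets held 6.07% to 6.98% of the signal on that side and 7.67% to 8.36% on the other, 48 of its genes were lower on that side, their median signal was 21915 and 0 are Meg3, Rian or Mirg; after quantile normalization it gave 0 genes, and the real split gave 2 with no other above 1. An effect of ascorbic acid may explain the pattern, as a hypothesis. Whether it acted through the imprint was not tested, since methylation was not analysed here. A restored imprint would be expected to lower the paternally expressed Dlk1, which was not lower on its brightest probe set (log2 difference 0.60 ± 0.18, SE). That probe set is of the _s_at class, and the other Dlk1 probe set, below the dim limit, was at -0.085 ± 0.27 (SE), so Dlk1 does not settle this.

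Tcf15, Mcts2 and H13 lie in one stretch of chromosome 2, with 7 other tested genes between Tcf15 and H13. The 27 tested neighbours had a median change of -0.021 (bootstrap 95% interval -0.06 to 0.04). Most of them flank the stretch, so this median cannot decide on a copy number difference of the stretch itself. The 7 genes between, read alone only after the values were seen, lay at -0.23 to 0.16 log2. A difference of the whole stretch is argued against, since an extra copy in every cell would give 0.585 if signal followed copy number. Whether the 1 Mcts2 probe set reads H13 transcripts was not settled. The test was chosen with both changes already seen, and other H13 transcript forms were not analysed. Mcts2 was higher while the brightest H13 probe set was lower, 1.45 log2 apart, so Mcts2 did not follow the transcripts read there. The only other H13 probe set above the dim limit was at -0.058 ± 0.17 (SE). Whether imprinted genes moved as a class stays open: with Mcts2 and H13 left out, 8 had an unadjusted limma p under 0.05, and 3 of the 35 splits, the real one included, gave as many, the highest other giving 9. Tcf15 is not on that list, and chance is not excluded for it by the count of genes above.

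The fibroblast and feeder-cell markers shifted lower as a set in camera (adjusted p = 3.88e-07; adjusted p = 0.589 with an estimated correlation). The markers moved together within groups (mean residual correlation 0.29, against -0.02 to 0.10 in 1000 random lists). Those lists were drawn from all tested genes, so any genes regulated together could exceed them. The correlation therefore does not single out feeder cells. Residual feeder cells may differ between clones, although preplating was meant to remove such cells, and this was not settled. Uneven spread of such clones between the groups is not excluded either, with an exact permutation p of 0.171 for the per-clone mean. The set calls as a whole do not exclude chance, since 10 of 35 splits gave as many lists as the real 4, the highest other giving 7, and 18 called the fibroblast list, the real split counted in both. Of the 46 markers 0 are on another list; Vim, an abundant member named after its values were seen, was at 13.53 log2 with and 13.72 without ascorbic acid, and expression of these markers by the iPS cells themselves stays open.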

How the results depend on the processing

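Testing every probe set under its own identifier was chosen after seeing the data; the other alternatives were planned. Named results and called lists were compared with 1016 alternatives: 980 kept their direction and side of the threshold, 27 lost the call, 5 gained one and 4 changed direction. Most of these results were far from the threshold and could hardly change side. Only the called genes and lists could lose a call. Of the 27 losses, 12 were of Tcf15 in 20 alternatives and 8 of the primed-state list in 22. The count of 3 genes became 1 without the intensity trend and 1 with robust estimation (Rian in both), and 2 to 4 under other gene-level settings and when a clone was left out. Over 27022 probe sets it was 13 (12 higher, 1 lower): 9 belong to Meg3, Rian and Mirg, and the lower one is a probe set of Shmt1 (named after its values were seen) at -0.59, while the gene's other probe sets lay at -0.10 to -0.14. The cause was not tested, except that probe sets of one gene count singly there. The count of 4 lists became 0 with an estimated correlation and 1 with fry, which also tests each list against no change and not against the other genes, and 3 to 5 when a clone was left out. The 3-gene difference of 1.99 spanned 1.79 to 2.21 when a clone was left out. Read from single Meg3 probe sets, it did not pass with 4 of the 11, where it was 0.31, 0.38, 0.29 and 0.36; the cause was not tested. Direction changed for Sox2 under quantile normalization (0.038), and when a clone was left out for Eif2s3y (-0.91 to 0.15), Uty (-0.81 to 0.30) and Xist (-0.0021 to 0.13), none of them called.

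Clone numbers do not pair the samples: deviations of same-numbered clones correlated at -0.17, -0.06, 0.01 and -0.02, and no clone with ascorbic acid correlated best with its own number. With the number as a replicate block, 3 genes and 4 lists passed, and the 3-gene difference was 1.99 with a sign-flip p of 0.125, the smallest that 4 pairs allow. Genes whose mean over all arrays lay under a signal of about 93.7 were not tested.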

Other observations

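The chromosome shifts and the choice of the imprinted genes named here came only after the result was seen; the imprinted list and the Y-linked genes were fixed beforehand.

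Further imprinted genes had an unadjusted limma p under 0.05 without passing over all genes or adjusted over the list alone, and are named here after their values were seen. Nnat, a neuronal membrane protein gene, read 850 ± 266 with and 437 ± 218 without ascorbic acid, and Gab1, a signalling adaptor, 4507 ± 1007 and 2903 ± 883 (SD, n = 4 each). Impact had a log2 change of 0.24. Lower with ascorbic acid were Kcnq1 (-0.72), the noncoding RNA Airn (-0.64), Gpr1 (-0.35) and the growth factor gene Igf2 (-0.24).

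Shifts of chromosomes were measured against the mean of the 8 clones, so a gain shared by all of them would not show. Among chromosomes 1 to 19 and X, the largest median shift in any clone was 0.058 log2. It was for chromosome X in clone 2 without ascorbic acid. An extra copy beside 2 in every cell would give 0.585 over clones without it, if signal followed copy number. For a chromosome X present in 1 copy it would give more. A gain in a small part of the cells was not tested. Chromosome Y was not part of that comparison. Its 4 named genes were all lowest in clone 2 with ascorbic acid: Eif2s3y read 418 there and 904 to 3934 in the other clones, Uty 65.8 and 183 to 797, Kdm5d 50.3 and 66.7 to 127, and Usp9y 15.2 and 66.9 to 114.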
